A study of Homo sapiens with 42 samples.

How the data were processed

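The series measured SW480TetOnAPC cells, a human colorectal cancer line in which doxycycline switches on full-length APC. Per the labels, cells given ethanol are APC-deficient and cells given doxycycline are APC-restored. The deposited data fall into 3 experiments: RNA-seq after 48 h, ribosome footprints with matched RNA-seq after 96 h in cells with a control shRNA or an shRNA against EIF2B5, and an shRNA drop-out screen with a start point (T0) and an end point (T15). Each group holds 3 libraries. The labels do not say whether the libraries of a group are separate cultures, so every p-value here measures only the spread between libraries.

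The 48 h experiment was read from the authors' deposited table alone, which gives per gene a log2 fold change, a mean log2 CPM (counts scaled to library size), a p-value and an adjusted p-value, with no value per library. Per the labels the submitters used Bowtie 0.12.8, edgeR, and the builds hg19 and GRCh37.p13. The adjusted values in the authors' table equalled a Benjamini-Hochberg adjustment of its p-values to within 2e-06. The direction of its fold change is not given in the sources used here. It was read as deficient minus restored, since APC itself has a negative value and since the table ran opposite to the 96 h RNA (Spearman -0.51 across 16900 genes, which are not independent replicates).

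For the 96 h RNA, the deposited values are expected counts, that is an estimated count of reads per gene with simple fractions and no scaling. The authors named STAR and the build hg38, and the counting method is not given in the sources used here. The authors deposited 1 table per replicate number, with 46832, 40472 and 35596 genes, and no table held a gene at 0 in all its libraries. A gene missing from a table was therefore taken as 0, giving 48717 genes, of which 34107 were in all tables. Library totals ran from 6.04 M reads (restored, control shRNA, replicate 3) to 36.99 M (restored, control shRNA, replicate 2).

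For the footprints, the deposited table holds estimated counts of reads mapped to the codons of 139788 open reading frames in 12 libraries, with a p-value of a generalized binomial test and a start codon score per frame, per the labels and the text file deposited with it. The p-value and score columns were not used. How frames were called is not given in the sources used here. The gene column of the deposited table named another gene for many frames: 77.87% of the frames carried a pair of gene identifiers, and for those the column held the gene of the frame's own transcript in 45.01%. Frames were therefore assigned to genes by transcript identifier, which was found for 97.67% of them. A gene's value was its most covered coding frame (annotated, truncated or variant), in 10232 genes. Library totals over all frames ran from 5.54 to 52.53 M reads, and over the coding frames used from 2.5 to 24.79 M, 47.32% of the deposited reads. The replicates of the footprints carry letters and those of the RNA carry numbers, and the labels give no link between them.

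For the screen, the deposited values are raw read counts of 27495 barcodes, all of them in the deposited library reference, against 5045 targets and with 21 barcodes for luciferase as controls. The authors named edgeR; how reads were matched to barcodes is not given in the sources used here. Totals per library ran from 6.82 to 14.79 M reads.

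Counts were tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test, after TMM scaling and filterByExpr (a minimum count of 10 and a minimum total of 15), with expected counts rounded to whole numbers. One model per experiment held all 12 libraries. Each comparison was adjusted on its own by Benjamini-Hochberg with a threshold of 0.05, and "called" means an adjusted p under it. Tested were 23673 genes in RNA, 9999 in footprints and 10162 in translational efficiency, which is the change in footprints minus the change in RNA, fitted as an interaction of assay and group. Log2 changes are restored minus deficient, or EIF2B5 shRNA minus control shRNA. Their standard error (SE) is an approximation, the absolute log2 change divided by the square root of the F statistic. CPM are mean ± SD over 3 libraries. Depth limits the precision of genes with few reads through these SEs. Drop-out is T15 minus T0, and its difference is doxycycline minus ethanol. A gene's screen value is the median over its shRNAs, tested with fry of limma 3.58.1, which asks whether the shRNAs of a gene move on balance in 1 direction, in 5043 targets with at least 3 shRNAs. The camera test of limma, which sets a gene's shRNAs against all others, was run beside it.

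Gene lists were tested with camera at its preset correlation of 0.01 between genes and again with a correlation estimated from the data, both adjusted by Benjamini-Hochberg over the lists of a comparison. The lists were fixed from textbook knowledge before the data were examined: WNT/beta-catenin targets, WNT pathway components, MYC targets of ribosome and nucleolar biogenesis, ATF4 and integrated stress response targets, cytoplasmic tRNA synthetases, mRNAs with upstream reading frames translated under eIF2 phosphorylation, cytoplasmic ribosomal proteins, other TOP mRNAs (mRNAs that start with a pyrimidine tract), eIF2 and eIF2B subunits and regulators, other initiation factors, cell cycle genes, apoptosis regulators, intestinal differentiation markers, the ER unfolded protein response, cholesterol biosynthesis, mitochondrially encoded mRNAs, interferon response, proteasome subunits, RNA polymerase II subunits and core splicing factors, and markers of fibroblasts and of blood cells (leukocyte genes and the red cell globin HBB) as other cell types. Fibroblast markers had too few measured members in RNA and were tested in the screen only. Over all comparisons, 66 list tests passed at the preset correlation and 12 with an estimated one; with a replicate block these counts were 78 and 3.

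The named genes also follow a rule fixed then: APC, MYC, AXIN2, ATF4, DDIT3 and EIF2B5 in every comparison, then the 6 called genes with the largest change in each direction at a mean log2 CPM of at least 3 and with groups that do not overlap, and up to 3 called members of each list with the smallest p. In the screen it names the 10 genes with the smallest fry p in each direction of the difference, the 8 that fell with the smallest fry p in each condition, the eIF2 and eIF2B subunits and kinases with MYC, CTNNB1 and APC, up to 3 called members of each list, and each EIF2B5 shRNA.

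In the RNA, libraries with the same replicate number resembled each other once group means were removed: the 18 correlations of same-number pairs across genes were 0.48 to 0.86 (median 0.73), against -0.67 to -0.04 for other pairs, and 12 of 12 libraries were closest to their own number. The RNA was thus also fitted with the replicate number as a block, and that value stands beside the unblocked one where it changes a call. In the footprints and the screen not every same-letter or same-number pair correlated above 0.1, the bound set for a pairing, so there the blocked fits are alternatives only. The bound is strict: 11 of 12 footprint libraries were closest to their own letter and 12 of 12 screen libraries to their own number. A pairing may thus be present there that the main fits ignore.

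The procedure was tested on simulated data with the dispersion (spread between libraries) of each unblocked fit. Simulated libraries were independent, without the shared replicate effects seen in the RNA, so the recovery rates hold only for such data. Of genes changed 4-fold between the control groups, the RNA fit recovered 8 of 96, the footprint fit 91 of 99 and the efficiency fit 47 of 99; of genes changed 2-fold, 0 of 97, 22 of 100 and 7 of 100. In the screen difference the fit recovered 59 of 100 shRNAs changed 2-fold and 100 of 100 changed 4-fold. A short list of genes called in RNA by the unblocked fit therefore says little about 2-fold changes. In RNA the common dispersion was 0.18 without the replicate block and 0.0272 with it, and recovery with paired replicates was not simulated.

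Alternatives tried were size factors by relative log expression (RLE) in place of TMM, no filter, a filter of 50 counts in 3 libraries, DESeq2 1.42.0, the compared groups alone, leaving out each replicate, the replicate block, other choices of reading frame, TMM within each assay, limma-voom for efficiency and a direct comparison at T15. Raw reads were not analysed here. No doxycycline-treated cells without the APC construct were analysed here.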

Results

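SW480 is a human colorectal cancer line with truncated APC, the scaffold of the complex that marks beta-catenin for degradation. In the SW480TetOnAPC cells of this series, doxycycline induces full-length APC and ethanol is the control. The experiments ask what restored APC does to RNA after 48 h and to RNA and ribosome footprints after 96 h, and what an shRNA against EIF2B5 adds to that. A drop-out screen asks which genes cells need for growth without APC but not with it. EIF2B5 encodes the catalytic subunit of eIF2B, which recharges the initiation factor eIF2 with GTP (chromosome 3, 184135358 to 184145311, plus strand, hg38). Every comparison of APC states is also one of doxycycline with ethanol.

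After 48 h, the authors' deposited table showed more APC RNA and less WNT target RNA in restored cells. In the authors' deposited table a negative log2 fold change was read as higher with restored APC, because APC (chromosome 5, 112043215 to 112181936, plus strand, hg19) stands there at -2.19, adjusted p = 4.1e-22. By that reading 3 feedback inhibitors of the WNT pathway were lower with restored APC in the authors' deposited table: AXIN2 (1.50, adjusted p = 1.3e-14), NKD1 (1.52) and APCDD1 (1.30). The growth regulator MYC was lower too (0.70 in the authors' deposited table, adjusted p = 0.00245). ATF4 (0.08, adjusted p = 0.965) and DDIT3 (0.44, adjusted p = 0.633), transcription factors of the integrated stress response, were not called in the authors' deposited table, nor was EIF2B5 (0.06, adjusted p = 1). Among called genes with a mean log2 CPM of at least 3, those highest with restored APC in the authors' deposited table were the matrix protease MMP9 (-4.26), the actin-binding SYNPO (-3.64), LAPTM5 (-3.61), the TNF family ligand CD70 (-3.37), FHL1 (-3.09) and RARRES3 (-3.09). Those lowest in the authors' deposited table were CPLX2 (2.34), the keratin KRT74 (2.27), the cytokine IL10 (1.89), the growth factor FGF3 (1.86), ADAMTS8 (1.85) and the neurotrophin receptor NTRK2 (1.85).

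Of 23 measured WNT/beta-catenin targets, 16 were called lower and 1 higher with restored APC in the authors' deposited table (median 0.88, camera adjusted p = 1.14e-25). MYC targets of ribosome and nucleolar biogenesis were lower as a group in the authors' deposited table, with 2 of 31 called and 4 when adjusted over the list alone (median 0.24, camera adjusted p = 0.0042). So were mRNAs with upstream reading frames, with 2 of 12 lower, IFRD1 at 1.13 among them, and 1 higher in the authors' deposited table (median 0.28, camera adjusted p = 0.0306). Interferon response genes were higher as a group in the authors' deposited table (median -0.47, camera adjusted p = 0.0127). Of 11 measured, 3 were higher and 1 lower in the authors' deposited table, with OASL at -1.88, MX1 at -0.82 and IFI27 at 1.13. All 3 measured markers of blood cells were higher too in the authors' deposited table, without a call as a group (median -0.98, camera adjusted p = 0.172). Among ATF4 targets the authors' deposited table called 5 lower (VLDLR, 1.36) and 3 higher (DDIT4, -1.05, and CEBPB, -0.92), without a call as a group (median 0.18, camera adjusted p = 0.0677). Of 9 intestinal markers the mucin MUC2 (-2.95) and the factor KLF4 (-0.84) were higher and CDX2 (0.63) lower in the authors' deposited table, also without a call as a group (camera adjusted p = 0.0677). No other list passed in the authors' deposited table, and an estimated correlation needs values per library. The authors' deposited table called 1412 of 22221 genes, 526 positive and 886 negative.

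After 96 h with the control shRNA, restored cells had more APC RNA. They had less RNA of MYC and, as groups by camera at its preset correlation, of WNT targets, MYC targets of ribosome biogenesis, ATF4 targets and tRNA synthetases. With an estimated correlation WNT targets did not pass (adjusted p = 0.106), and with the block besides the other 3 did not (0.164, 0.224 and 0.135). APC RNA rose to 1750 ± 272 from 92.7 ± 21.3 CPM (read counts scaled to library size, mean ± SD, n = 3; log2 4.24, SE 0.32, adjusted p = 0.000236). MYC fell to 101 ± 37.7 from 312 ± 23.5 CPM (log2 -1.63, SE 0.26, adjusted p = 0.0105), lower in 3 of 3 restored libraries than in every deficient one. AXIN2 was at 88.0 against 299 CPM (log2 -1.76, SE 0.41, adjusted p = 0.0591), and with replicates as a block it fell by 1.84 (adjusted p = 6.49e-05). ATF4 was at 97.1 against 182 CPM (log2 -0.91, SE 0.43, adjusted p = 0.421) and fell by 0.78 with the block (adjusted p = 0.0148). DDIT3, a pro-apoptotic factor downstream of ATF4, was at 28.1 against 98.4 CPM (log2 -1.81, SE 0.54, adjusted p = 0.14) and fell by 1.58 with the block (adjusted p = 0.00202). EIF2B5 itself was not called (log2 -0.16, SE 0.26, adjusted p = 0.98).

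**Figure D1:**
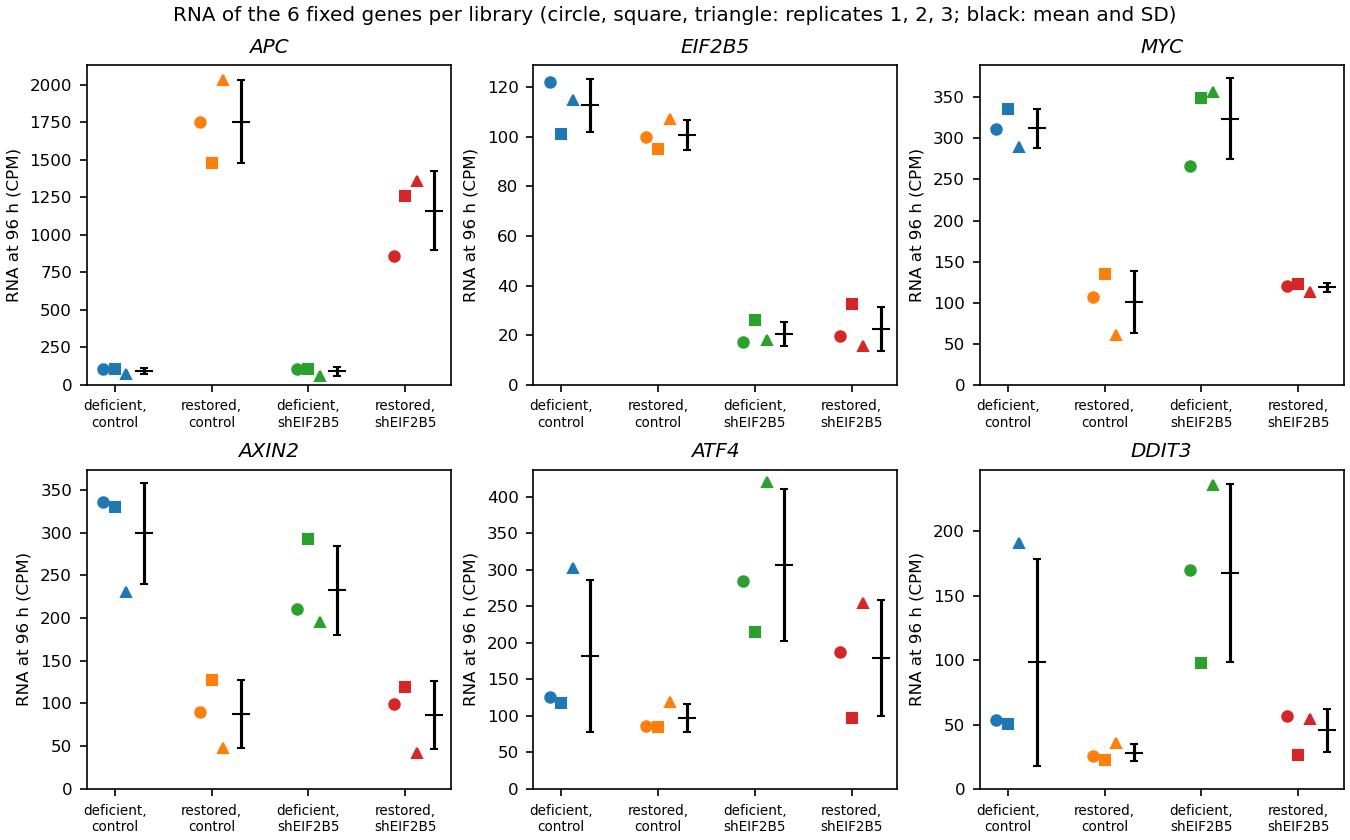
RNA at 96 h of APC, EIF2B5, MYC, AXIN2, ATF4 and DDIT3 in CPM (vertical axes, linear from 0) in the 4 groups of APC state and shRNA. Circle, square and triangle are replicates 1, 2 and 3, and the black bars give mean and SD. APC is high in both restored groups, MYC and AXIN2 are lower there, and EIF2B5 is low in both groups with its shRNA.

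Of 24 WNT/beta-catenin targets 4 fell in the 96 h RNA and 0 rose by edgeR, or 15 and 2 when adjusted over the list alone. The stem cell factor ASCL2 fell by 2.50 (log2, SE 0.42, adjusted p = 0.0144) and the cyclin CCND1 by 0.93 (SE 0.18, adjusted p = 0.0261). The list fell as a group (median -1.48, camera adjusted p = 1.09e-15; adjusted p = 0.106 with an estimated correlation). Of 36 MYC targets of ribosome and nucleolar biogenesis 4 fell, 14 when adjusted over the list alone, and all 36 were negative. Their median was -0.60 (camera adjusted p = 9.33e-15, 0.0417 with an estimated correlation). Examples are the pseudouridine synthase DKC1 (-0.76, SE 0.15) and the ribosomal protein methyltransferase PRMT3 (-0.85, SE 0.15).

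Of 36 ATF4 and integrated stress response targets 7 fell, 17 when adjusted over the list alone, and 34 were negative. Their median was -0.92 (camera adjusted p = 1.25e-16, 0.046 with an estimated correlation). The serine synthesis enzyme PSAT1 (-1.49, SE 0.30), the transcription factor ATF3 (-1.17, SE 0.25) and the tRNA exporter XPOT (-1.13, SE 0.23) were among them. Of 20 cytoplasmic tRNA synthetases, which charge tRNAs with amino acids, GARS1 (-1.11) and MARS1 (-1.03) fell, 9 fell when adjusted over the list alone, and all 20 were negative. Their median was -0.57 (camera adjusted p = 9.25e-11, 0.046 with an estimated correlation). Of 15 mRNAs with upstream reading frames IFRD1 fell (-1.92, SE 0.32), and 4 when adjusted over the list alone (median -0.52, camera adjusted p = 3.88e-06, 0.046 with an estimated correlation). Of 19 eIF2 and eIF2B subunits and regulators 17 were negative and none was called (median -0.39, camera adjusted p = 0.000648, 0.046 with an estimated correlation). With replicates as a block and an estimated correlation, MYC targets had adjusted p = 0.164, ATF4 targets 0.224, tRNA synthetases 0.135, mRNAs with upstream frames 0.172 and the eIF2 list 0.224.

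Also lower as groups in the 96 h RNA, with no member called, were cell cycle genes (median -0.37, camera adjusted p = 1.06e-05), other initiation factors (-0.31, 0.0016), proteasome subunits (-0.26, 0.0046) and RNA polymerase II subunits and splicing factors (-0.26, 0.0119). In that order they had adjusted p = 0.189, 0.278, 0.588 and 0.238 with an estimated correlation. Without 1 of the 6 libraries proteasome subunits passed in 4 of 6 fits and RNA polymerase II and splicing in 5. Without deficient replicate 3 the medians of initiation factors and proteasome subunits were -0.15 and -0.10. Cholesterol biosynthesis was higher as a group, 19 of 20 members being positive (median 0.27, camera adjusted p = 0.0157; adjusted p = 0.588 with an estimated correlation). Of 17 interferon response genes the antiviral GTPase MX1 rose (1.25) and IFI27 fell (-2.32), or 8 and 3 when adjusted over the list alone. Their median was 0.50 (camera adjusted p = 0.00346; adjusted p = 0.106 with an estimated correlation) and fell to 0.25 without deficient replicate 1. Cholesterol genes passed in 4 and interferon genes in 5 of the 6 fits without 1 library. Markers of blood cells, from a list of leukocyte genes and the red cell globin HBB, moved with all these groups. All 5 measured markers were positive (median 1.15, camera adjusted p = 6.17e-05, 0.0417 with an estimated correlation; with the block, 0.135). Their levels were near the detection limit, and of the 5 only HBB, which is no leukocyte gene, was called, at 4.09 ± 1.28 against 0.0593 ± 0.103 CPM (log2 5.92, SE 0.90, adjusted p = 0.00908).

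Cytoplasmic ribosomal proteins did not pass in the 96 h RNA (79 members, median -0.09, camera adjusted p = 0.107). With the block their median was -0.13 (camera adjusted p = 0.00797; adjusted p = 0.788 with an estimated correlation). Not passing either were other TOP mRNAs (median -0.16, camera adjusted p = 0.151), apoptosis regulators (0.05, 0.994), the ER unfolded protein response (-0.06, 0.66) and mitochondrially encoded mRNAs (-0.15, 0.539). The same holds for WNT pathway components, in which APC alone was called (-0.03, 0.916), and for intestinal markers, of which CDX2 fell by 1.39 (median 0.41, camera adjusted p = 0.832). Without 1 library ribosomal proteins passed in 3 of 6 fits (medians -0.50 to 0.15), other TOP mRNAs in 2 (-0.38 to -0.05) and mitochondrial mRNAs in 1 (-0.54 to 0.29). Intestinal markers (0.09 to 1.28) and WNT pathway components (-0.36 to 0.17) passed in 0. The largest changes were ranked among called genes with a mean log2 CPM of at least 3 and groups that do not overlap. Those that rose most were the urea transporter SLC14A1 (log2 4.40), SYT12 (4.34), the MHC class II chain HLA-DRB1 (4.28, uncertain because its paralogs share reads), APC, the complement factor C3 (4.27) and the myelin protein PLLP (4.25). Those that fell most were the calcium channel TRPV6 (-5.82), the serine protease GZMB (-5.29), the glutamate transporter SLC1A2 (-4.36), the manganese exporter SLC30A10 (-3.88), the anion exchanger SLC26A4 (-3.58) and FGF3 (-3.40).

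By edgeR 443 of 23673 genes were called in the 96 h RNA, 250 up and 193 down. With replicates as a block 3692 were called (1681 up, 2011 down), which included all 443, and DESeq2 called 1217. A fit of these 6 libraries alone called 70. Leaving out a deficient library gave 178, 186 and 132 calls (replicates 1, 2 and 3), and leaving out a restored one 168, 210 and 254. The overlap with 48 h was counted among the 16900 genes measured at both times only. Of those called higher with restored APC in the authors' deposited table (853) and at 96 h (212), 132 were in both, where independent lists would share 10.7. Of those lower in the authors' deposited table (478) and at 96 h (161), 104 were in both, where independent lists would share 4.6.

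**Figure D2:**
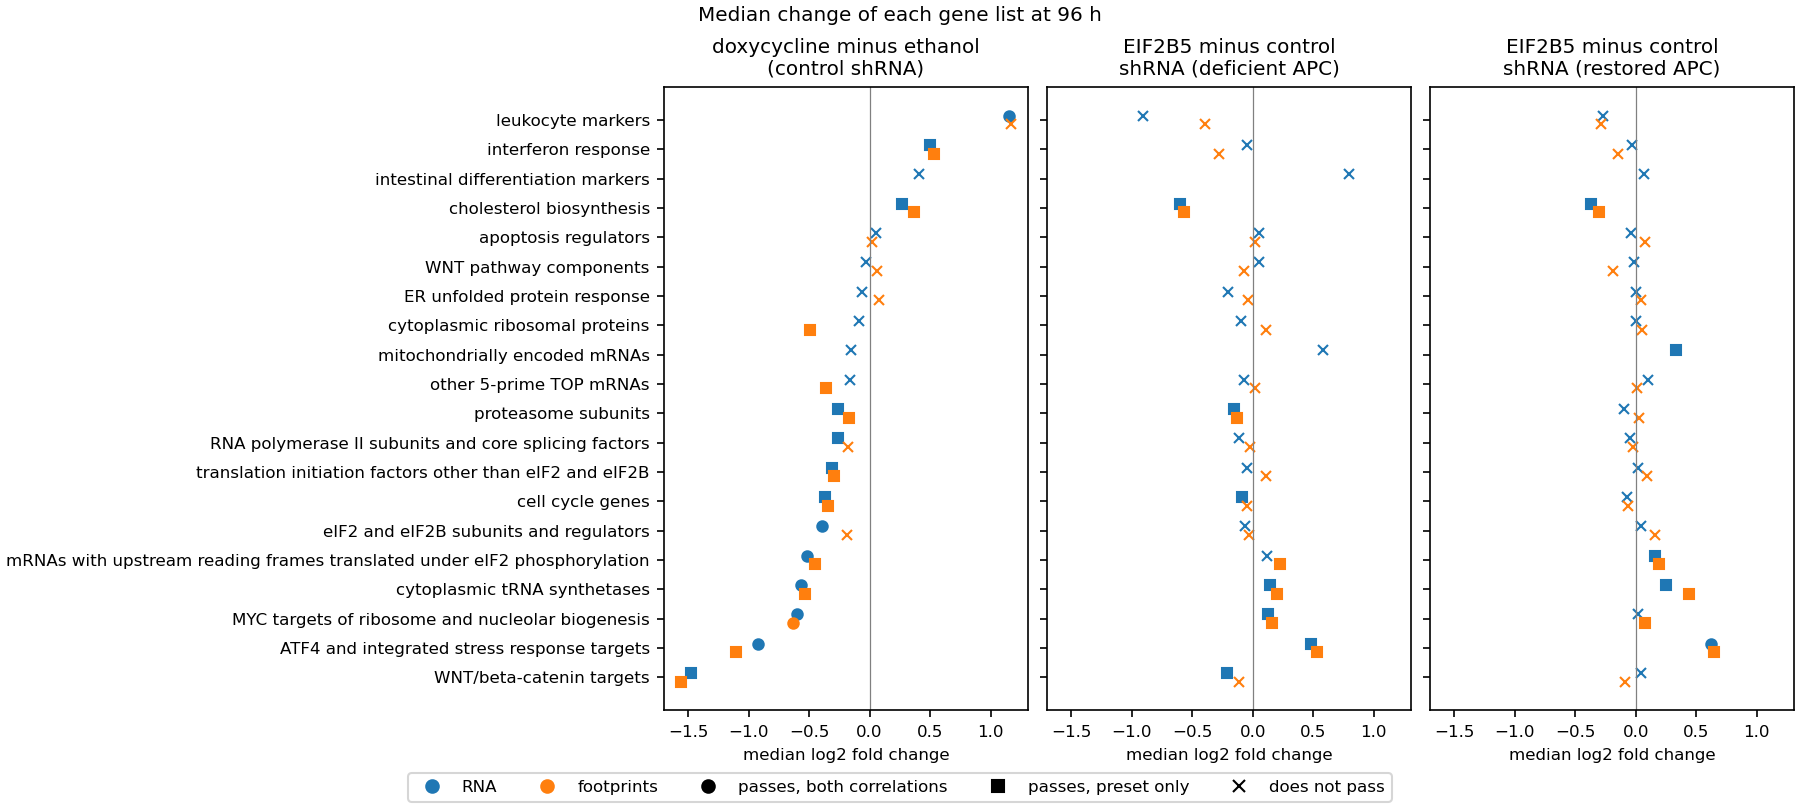
Median log2 fold change of each gene list (horizontal axis) at 96 h in RNA (blue) and footprints (orange), for doxycycline minus ethanol and for the EIF2B5 shRNA minus the control shRNA in each APC state. Circles pass camera with the preset and the estimated correlation, squares with the preset one only, and crosses do not pass. ATF4 targets lie at -0.92 and -1.10 with doxycycline and between 0.48 and 0.65 with the EIF2B5 shRNA.

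Ribosome footprints, which count ribosomes on coding frames, showed MYC targets lower as a group with restored APC at 96 h, as in RNA. WNT targets, ATF4 targets and ribosomal protein mRNAs were lower at the preset correlation only (adjusted p = 0.131, 0.131 and 0.156 with an estimated one). APC footprints rose to 475 ± 208 from 26.1 ± 3.45 CPM (log2 4.18, SE 0.38, adjusted p = 2.76e-05). MYC (-1.64, SE 0.26, adjusted p = 0.00298), AXIN2 (-2.03, SE 0.40, adjusted p = 0.0112) and ATF4 (-2.09, SE 0.53, adjusted p = 0.041) fell, each lower in 3 of 3 restored libraries than in every deficient one. The most covered coding frame of ATF4 is a truncated one. DDIT3 (-1.82, SE 0.49, adjusted p = 0.0525) and EIF2B5 (-0.08, SE 0.38, adjusted p = 0.946) were not called. With the footprint letter as a block, an alternative fit, DDIT3 fell by 1.62 and was called (adjusted p = 0.0199). Of 23 WNT/beta-catenin targets 10 fell and 0 rose by edgeR, or 16 and 2 when adjusted over the list alone, with NKD1 at -2.19 and the WNT antagonist DKK1 at -1.95. Their median was -1.56 (camera adjusted p = 3.79e-13; adjusted p = 0.131 with an estimated correlation). Of 33 ATF4 targets 6 fell, 20 when adjusted over the list alone (median -1.10, camera adjusted p = 2.92e-14; adjusted p = 0.131 with an estimated correlation). Among them were SLC7A5 (-1.17) and SLC3A2 (-1.18), the chains of a leucine transporter, and VLDLR (-2.30). Of 36 MYC targets of ribosome and nucleolar biogenesis 5 fell, 20 when adjusted over the list alone, with the nucleolar chaperone NOLC1 at -1.01, PA2G4 at -0.75 and PRMT3 at -0.85. Their median was -0.63 (camera adjusted p = 8.21e-15, 0.0123 with an estimated correlation).

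All 67 measured cytoplasmic ribosomal proteins were negative in footprints. Their median was -0.49 (camera adjusted p = 1.49e-12; adjusted p = 0.156 with an estimated correlation). Other TOP mRNAs, 13 of 14 negative, had a median of -0.36 (camera adjusted p = 0.00322; adjusted p = 0.354 with an estimated correlation). Lower as groups were also tRNA synthetases (median -0.53, camera adjusted p = 5.04e-06), mRNAs with upstream frames (-0.45, 0.000801, with IFRD1 at -1.69), cell cycle genes (-0.34, 0.00116, with the helicase subunit MCM6 at -0.69), other initiation factors (-0.29, 0.00322) and proteasome subunits (-0.17, 0.025). In that order they had adjusted p = 0.156, 0.131, 0.24, 0.354 and 0.522 with an estimated correlation. Lower in RNA but not passing in footprints were the eIF2 and eIF2B list (median -0.19, camera adjusted p = 0.0552) and RNA polymerase II and splicing (-0.18, 0.0505). Without 1 library each of these 2 lists passed in 3 of 6 footprint fits (medians -0.31 to -0.08 and -0.21 to -0.11), so this contrast with RNA turns on single libraries. Cholesterol biosynthesis was higher, 20 of 20 members being positive (median 0.37, camera adjusted p = 0.00252; adjusted p = 0.354 with an estimated correlation). So was the interferon response (median 0.53, camera adjusted p = 0.0368; adjusted p = 0.156 with an estimated correlation), in which RIGI (1.48) and IFIT1 (2.69) rose and IFI27 (-2.49) fell. Without 1 library the interferon response passed in 3 of 6 fits (medians 0.26 to 0.80), proteasome subunits in 3 (-0.31 to -0.04), and other TOP mRNAs (-0.55 to -0.22) and initiation factors (-0.44 to -0.20) in 4 each. Upstream-frame mRNAs had -0.76 without restored B. The 3 measured markers of blood cells were positive and did not pass (median 1.17, camera adjusted p = 0.0601). By the same limits on level and overlap as in RNA, the largest rises in footprints were of the bactericidal protein BPI (7.09), SLC14A1 (5.45), SYT12 (5.28), C3 (4.71), MMP9 (4.39) and HLA-DRB1 (4.24). The largest falls were of GZMB (-7.20), UGT1A3 (-4.57), UGT1A5 (-4.56), FGF3 (-3.73), the cytokine IL24 (-3.66) and the guidance ligand SLIT1 (-3.60). UGT1A3 and UGT1A5 share exons, so their reads cannot be assigned with certainty.

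By edgeR 380 of 9999 genes were called in footprints, 231 up and 149 down, and 816 by DESeq2. Leaving out a library gave 203 (deficient A), 206 (deficient C), 216 (restored A) and 175 (restored C) calls. Across 9887 genes the changes in RNA and footprints had a Spearman correlation of 0.80, in which genes are not independent replicates. Among these 9887 genes 273 were called in RNA and 373 in footprints. Of them 166 were in both, all in the same direction, where independent lists would share 5.2 in the same direction.

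**Figure D3:**
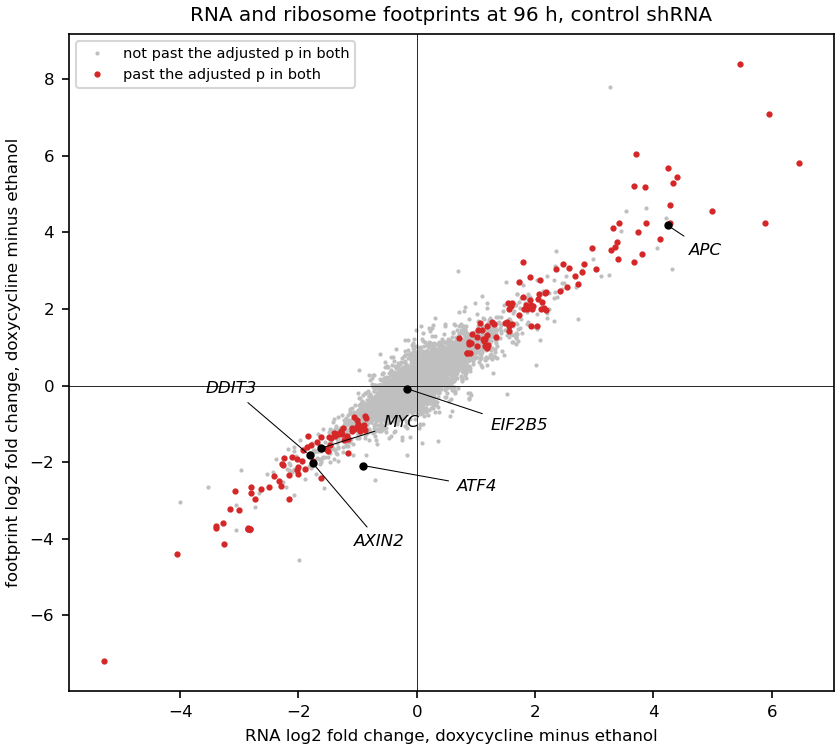
Log2 fold change of each gene in ribosome footprints (vertical axis) against RNA (horizontal axis), doxycycline minus ethanol with the control shRNA at 96 h. Red points are the 166 genes called in both, grey points all others, and black points 6 genes fixed beforehand. ATF4 lies lower in footprints (-2.09) than in RNA (-0.91).

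Translational efficiency, the footprint change beyond the RNA change, was lower with restored APC for ribosomal proteins as a group, 66 of 67 being negative (median -0.52, camera adjusted p = 1.87e-21; adjusted p = 0.747 with an estimated correlation). It was lower for other TOP mRNAs, 13 of 14 being negative (median -0.37, camera adjusted p = 0.00108; adjusted p = 0.747 with an estimated correlation). MYC targets of ribosome and nucleolar biogenesis (-0.14, camera adjusted p = 0.00696) and ATF4 targets (-0.12, camera adjusted p = 0.032) were lower by less. These had adjusted p = 0.747 and 0.894 with an estimated correlation. No single gene was called: edgeR gave 0 of 10162 genes (42 at an unadjusted p under 0.05), DESeq2 0 and limma-voom 0. Without any change a share of 0.05 of the genes would be expected under that p, far more than 42. The p-values of this edgeR fit thus ran high, and 0 calls do not show that efficiency was unchanged. ATF4 stood at -1.29 (SE 0.74, adjusted p = 1). The RNA side of the ribosomal proteins moved with single libraries, the median RNA change being -0.50 without restored replicate 3 and 0.15 without deficient replicate 3. No list passed in the efficiency changes with the EIF2B5 shRNA.

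The EIF2B5 shRNA lowered its own target RNA, and with it ATF4 targets were higher and cholesterol synthesis genes lower as groups in both APC states at the preset correlation. With an estimated one only ATF4 targets in restored cells passed (adjusted p = 0.0228; with the block, 0.203). In deficient cells EIF2B5 RNA fell to 20.4 ± 4.87 from 113 ± 10.7 CPM (log2 -2.46, SE 0.28, adjusted p = 0.049). In restored cells it was at 22.5 ± 8.89 against 101 ± 5.99 CPM, lower in 3 of 3 libraries than in every control (log2 -2.16, SE 0.27, adjusted p = 0.159). With replicates as a block it fell there by 2.19 (adjusted p = 0.00457). Of 36 ATF4 targets 32 were positive in deficient cells, 1 of them passing when adjusted over the list alone (median 0.48, camera adjusted p = 1.07e-17; adjusted p = 0.116 with an estimated correlation). In restored cells all 36 were positive and 10 passed when adjusted over the list alone. Their median was 0.62 (camera adjusted p = 9.64e-41, 0.0228 with an estimated correlation, 0.203 with the block besides). ATF4 RNA itself had log2 0.75 (SE 0.43) in deficient and 0.89 (SE 0.43) in restored cells, each with adjusted p = 1. Cholesterol biosynthesis genes were negative in 20 of 20 cases in both states (medians -0.60 and -0.37, camera adjusted p = 5.64e-20 and 6.21e-12). They had adjusted p = 0.116 and 0.201 with an estimated correlation. Without 1 library the median of ATF4 targets in deficient cells fell as low as 0.29, and that of cholesterol genes in restored cells ran from -0.69 to -0.19, each passing in 6 of 6 fits. The tRNA synthetases were higher in restored cells, 5 passing when adjusted over the list alone (median 0.25, camera adjusted p = 3.94e-11; adjusted p = 0.116 with an estimated correlation). They were higher in deficient cells too (0.14, camera adjusted p = 0.0096; adjusted p = 0.504 with an estimated correlation), where they passed in 4 of 6 fits without 1 library (0.06 to 0.33). In restored cells all 6 such fits passed (up to 0.41). MYC RNA (0.05 and 0.23) and APC RNA in restored cells (-0.59, SE 0.28, adjusted p = 1) were not called.

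Smaller shifts with the EIF2B5 shRNA in the RNA of deficient cells were lower WNT targets (median -0.21, camera adjusted p = 0.0326), cell cycle genes (-0.09, 0.0196) and proteasome subunits (-0.15, 0.048), and higher MYC targets (0.13, 0.0407). In that order they had adjusted p = 0.676, 0.504, 0.676 and 0.504 with an estimated correlation. Without 1 library they passed in 2, 3, 3 and 3 of 6 fits, and the medians of proteasome subunits (-0.29 to 0.01) and MYC targets (0.00 to 0.20) reached 0. In restored cells mitochondrially encoded mRNAs (13 of 13 positive, 0.33, 0.00367) and mRNAs with upstream frames (0.16, 0.0322) were higher. These had adjusted p = 0.884 and 0.508 with an estimated correlation. Without 1 library they passed in 3 and 2 of 6 fits, with medians of -0.09 to 0.78 and 0.04 to 0.42. Ribosomal proteins did not pass in either state, but without 1 library passed in 4 of 6 fits in deficient (-0.34 to 0.16) and 5 in restored cells (-0.39 to 0.44). By edgeR 1 gene, EIF2B5, was called in deficient cells (645 at an unadjusted p under 0.05, DESeq2 40), and 0 in each fit without one of the 6 libraries. In restored cells edgeR called 0 genes (411 at an unadjusted p under 0.05, DESeq2 20). Both unadjusted counts, 645 and 411, lie below a share of 0.05 of the tested genes, so few calls do not show that little changed. With replicates as a block the called genes numbered 191 (45 up, 146 down) in deficient and 14 (9 up, 5 down) in restored cells.

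In footprints, ATF4 targets were again higher and cholesterol genes lower with the EIF2B5 shRNA at the preset correlation, in no case with an estimated one, and no single gene was called. ATF4 itself had log2 1.34 (SE 0.51, adjusted p = 0.939) in deficient and 1.77 (SE 0.52, adjusted p = 1) in restored cells. DDIT3 had 1.67 (SE 0.48, adjusted p = 0.823) and 1.32 (SE 0.48, adjusted p = 1). In deficient cells 29 of 33 ATF4 targets were positive and 5 passed when adjusted over the list alone (median 0.53, camera adjusted p = 5.92e-13; adjusted p = 0.212 with an estimated correlation). In restored cells 32 were positive and 7 passed when adjusted over the list alone (median 0.65, camera adjusted p = 5.49e-31; adjusted p = 0.0767 with an estimated correlation). Cholesterol genes were negative in 20 of 20 cases in each state (medians -0.57 and -0.30, camera adjusted p = 5.65e-12 and 4.48e-08). They had adjusted p = 0.212 and 0.229 with an estimated correlation. Without 1 library both lists passed in 6 of 6 fits in each state. In deficient cells their medians came as near 0 as 0.34 and -0.37, and in restored cells cholesterol genes ran from -0.55 to -0.20. Higher in both states were tRNA synthetases (0.20 and 0.44, camera adjusted p = 0.0348 and 1.18e-07), mRNAs with upstream frames (0.23 and 0.19, 0.00873 and 0.0425) and MYC targets (0.16 and 0.08, 0.00873 and 0.0224). In that order they had adjusted p = 0.725, 0.229, 0.212, 0.38, 0.348 and 0.392 with an estimated correlation. Without 1 library mRNAs with upstream frames passed in 3 of 6 fits in deficient cells (medians 0.08 to 0.41) and 2 in restored cells (0.07 to 0.29). The tRNA synthetases passed in 3 and 6 (0.08 to 0.36 and 0.23 to 0.56) and MYC targets in 4 and 3 (0.10 to 0.23 and -0.01 to 0.14). Proteasome subunits were lower in deficient cells (-0.13, camera adjusted p = 0.025; adjusted p = 0.725 with an estimated correlation), and in 2 of 6 fits without 1 library. EIF2B5 footprints on its most covered frame had log2 -0.90 (SE 0.40, adjusted p = 0.947) and -1.40 (SE 0.39, adjusted p = 1). Over all frames of the gene they fell by 2.22 (SE 0.24, adjusted p = 0.00232) in deficient and 1.88 (SE 0.233, adjusted p = 0.0115) in restored cells. By edgeR 0 genes were called in either state on the most covered frames (514 and 141 at an unadjusted p under 0.05), against 16 and 6 by DESeq2. The 141 in restored cells lie below a share of 0.05 of the tested genes.

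Whether the EIF2B5 shRNA acts differently in restored and deficient cells was tested as an interaction. In RNA the shRNA effect, not the level, was higher in restored than in deficient cells for 3 lists. These were WNT targets (median difference 0.28), ATF4 targets (0.29) and cholesterol genes (0.22), each with camera adjusted p = 0.0276. Each had adjusted p = 0.869 with an estimated correlation. The interaction was not refitted without single libraries. In restored cells the shRNA effect on WNT targets ran from -0.24 to 0.49 without 1 library and passed in 3 of 6 fits. In footprints and efficiency no list passed. By edgeR 0 genes were called in RNA (422 at an unadjusted p under 0.05), footprints (124) and efficiency (38), and by DESeq2 0 in each.

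In the screen, shRNAs against ribosomal proteins, the proteasome, RNA polymerase II and splicing, and tRNA synthetases were lost as groups between T0 and T15 in both conditions, by camera at its preset correlation. With an estimated one only the proteasome passed in both (adjusted p = 0.0118 and 0.000406). Examples of the loss in ethanol were the proteasome subunit PSMA1 (median log2 -3.67 over its shRNAs), the nuclear transport GTPase RAN (-3.59), the ubiquitin ligase subunit RBX1 (-3.05), the eIF2 subunit EIF2S2 (-2.93), PSMA6 (-2.85), the tRNA synthetase VARS (-2.83) and the ribosomal protein RPL4 (-2.63). With doxycycline these medians were -3.17, -2.77, -2.26, -2.46, -2.40, -2.50 and -2.32 in the same order. By fry, 15 of 17 ribosomal protein genes fell in ethanol and 16 with doxycycline, as did 27 and 26 of 29 proteasome subunits. Of 14 genes for RNA polymerase II and splicing 13 and 10 fell, and of 20 tRNA synthetases 16 and 11. MYC had 0.35 in ethanol and 0.56 with doxycycline, and CTNNB1, beta-catenin, -0.06 and -0.51.

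Over shRNAs, camera adjusted p was 4.44e-20 in ethanol and 1.37e-11 with doxycycline for ribosomal proteins (medians -1.93 and -1.69), with adjusted p = 0.0755 and 0.0775 with an estimated correlation. For the proteasome it was 3.14e-24 and 1.37e-11 (medians -1.85 and -1.36; 0.0118 and 0.000406 with an estimated correlation). For RNA polymerase II and splicing it was 2.2e-08 and 0.00713 (medians -0.86 and -0.70; adjusted p = 0.046 and 0.0775 with an estimated correlation). For tRNA synthetases it was 0.000655 and 0.038 (medians -0.33 and -0.46; adjusted p = 0.046 and 0.0775 with an estimated correlation). No other list passed in either condition. Of the markers of other cell types, 7 fibroblast genes had 3 up and 1 down in ethanol (camera adjusted p = 0.82), and 7 blood cell genes 4 up and 1 down (0.82).

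By edgeR 19435 shRNAs changed in ethanol (10587 up, 8848 down) and 20569 with doxycycline (10468 up, 10101 down). By fry 3284 and 3568 of 5043 genes changed, while camera, which compares a gene with all others, called 46 and 11. Of the fry calls in ethanol 52.3% were up by TMM scaling and 41.1% by RLE. The 21 luciferase controls had medians of -0.15 and -0.14 (SD 1.08 and 1.31, against 0.97 and 1.06 over all shRNAs). Of these controls 6 rose and 7 fell in ethanol, and 6 rose and 9 fell with doxycycline, by the same edgeR call. A called shRNA alone is therefore no sign of an effect of its target. At T0 doxycycline and ethanol differed in 0 shRNAs by edgeR (4 at an unadjusted p under 0.05, DESeq2 0). They differed in 0 genes by fry (18 at an unadjusted p under 0.05) and in 2 by camera. Pairs of T0 libraries lay near counting noise (chi-square per degree of freedom 1.28 to 2.69). Pairs of T15 libraries of a group differed by more (6.71 to 15.19). The fit shares 1 spread over T0 and T15. The p-values of drop-out and of its difference, those of EIF2B5 below included, can therefore be too small.

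EIF2B5 had the largest median difference in drop-out among the 5043 genes. Its shRNAs were depleted in ethanol by fry (median log2 -1.22, SD 1.19 over 5 shRNAs, fry adjusted p = 5.67e-05) and not called with doxycycline (0.16, fry adjusted p = 0.167). By camera, which sets them against all other shRNAs, the loss in ethanol was not called (camera adjusted p = 0.538). The difference was 1.33 (SD 0.52, fry adjusted p = 0.0105, camera adjusted p = 0.0187). Barcode CLL-H-008985 had -1.22 in ethanol and 0.28 with doxycycline (difference 1.50, SE 0.32, adjusted p = 0.00671), and CLL-H-008986 had -1.54 and -0.08 (1.46, SE 0.26, adjusted p = 0.00244). For CLL-H-008987 the values were -3.17 and -1.85 (1.33, SE 0.37, adjusted p = 0.0275), and for CLL-H-008988 -0.99 and 0.16 (1.15, SE 0.27, adjusted p = 0.0121). The fifth, CLL-H-008989, was not called in either condition (0.12 and 0.35) or for the difference (0.23, SE 0.24, adjusted p = 0.572). Without doxycycline T15 replicate 1 the doxycycline value itself became a call (-0.04, fry adjusted p = 0.00314).

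Of 13 genes of the eIF2 and eIF2B list in the library, EIF2B5 and EIF2S2 (0.59, fry adjusted p = 0.0192) had a positive called difference. BZW1 (-0.46, fry adjusted p = 0.0157), a regulator of start codon choice, had a negative one, as did EIF5 (-0.10, fry adjusted p = 0.0353), the GTPase activator of eIF2, which was singled out after its values were seen. The other members were not called: EIF2S1 (0.21), EIF2S3 (0.24), EIF2B1 (0.06), EIF2B2 (-0.22), EIF2B4 (0.22), and the eIF2 kinases EIF2AK1 (0.05), EIF2AK2 (-0.16), EIF2AK3 (-0.30) and EIF2AK4, also called GCN2 (-0.09). EIF2S2 was also among the 47 genes of the screen with an ethanol median under -2. Their median difference was 0.41, so the 0.59 of EIF2S2 need not be particular to eIF2.

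**Figure D4:**
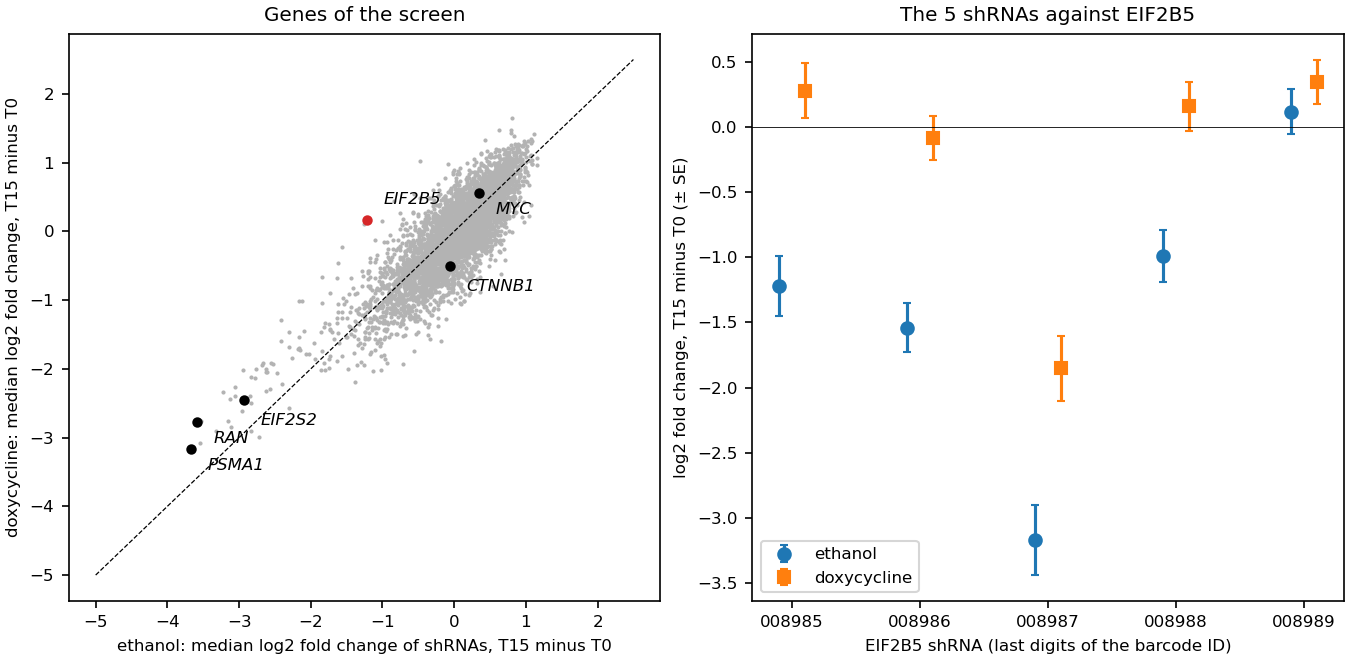
Left, median log2 fold change from T0 to T15 of each gene's shRNAs with doxycycline (vertical axis) against ethanol (horizontal axis), a dot per gene, with the diagonal dashed. Right, the same change for each of the 5 EIF2B5 shRNAs, circles for ethanol and squares for doxycycline, bars for the SE. EIF2B5 (red) lies above the diagonal by 1.33, and 4 of its shRNAs lie lower in ethanol by 1.15 to 1.50.

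Other genes with a positive difference were the anti-apoptotic BCL2L1 (0.96, fry adjusted p = 0.00651), with medians of -0.33 in ethanol and 0.49 with doxycycline, and the splicing factors SNRNP200 (0.91) and SNRPD2 (0.77). The proteasome subunit PSMB5 (0.64) had medians of 0.02 and 0.11. The RNA polymerase II subunit POLR2B (0.78, 11 of 27 shRNAs up) was called by camera too (adjusted p = 0.000376). PAWR, a pro-apoptotic factor singled out after its values were seen as the third gene called by camera, had a difference of 1.13 (camera adjusted p = 0.0391). More negative with doxycycline were IL17RE (-0.29), IRF5 (-0.47), DTX3L (-0.55), GNPDA1 (-0.69) and IFI44 (-0.69). Proteasome subunits were lost less as a group, with 8 of 29 genes up by fry and 13 when adjusted over the list alone (median over shRNAs 0.38, camera adjusted p = 3.56e-07; adjusted p = 0.0775 with an estimated correlation). So were RNA polymerase II and splicing, with 3 of 14 genes and 4 when adjusted over the list alone (0.34, camera adjusted p = 1.15e-05; adjusted p = 0.0775 with an estimated correlation). Of 96 shRNAs against ribosomal proteins 79 were positive (median 0.35, camera adjusted p = 0.00403; adjusted p = 0.64 with an estimated correlation). These medians are near the 0.41 of the 47 genes with the strongest loss in ethanol, whatever their list. The 47 were picked by the ethanol values that the difference contains, which alone can raise that median.

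By edgeR 3219 shRNAs differed in drop-out (1562 up, 1657 down) and by fry 500 genes (229 up, 271 down), against 3 up by camera. The counts by edgeR and fry can be too high, since the fit shares 1 spread between the T15 libraries and the more alike T0 libraries. Of the called shRNAs 48.5% were up by TMM scaling and 60.2% by RLE, and of the genes 45.8% and 67.2%. Without doxycycline T15 replicate 3, which stands apart from the others, 6575 shRNAs and 918 genes differed, and without one of the 6 T0 libraries 1513 to 1714 shRNAs and 177 to 264 genes. EIF2B5 passed without each of the 12 libraries (difference 1.22 to 1.56, fry adjusted p = 0.00648 to 0.0353).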

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

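The tests below of the T0 difference, of the other 4 EIF2B5 shRNAs, of doxycycline itself, of mitochondrial translation, of composition and of low footprint depth were chosen after the result they bear on was seen. For a weaker drop-out of all depleted shRNAs, only the count of matched genes with a difference as large as that of EIF2B5 was fixed before. The median difference of the matched genes, how many were positive, and the values of the genes with the strongest loss were not part of that fixed test. The other tests were fixed before.

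The test of the difference in drop-out, doxycycline minus ethanol, gave 3219 shRNAs and 500 genes that differed between the conditions. For EIF2B5, 4 of 5 shRNAs differed, with a median of 1.33. Of the genes named by the fixed rule, those of the translation and stress lists with a positive difference were EIF2S2 (0.59), PSAT1 (0.56), YARS (0.49), CALR (0.28) and EEF1D (0.15). Those with a negative one were BZW1 (-0.46), ALDH18A1 (-0.31) and CARS (-0.10), to which EIF5 (-0.10), singled out after its values were seen, can be added. Of the proteasome, PSMB5 (0.64), PSMC1 (0.48) and PSMB6 (0.36) were positive, and of RNA polymerase II and splicing SNRNP200 (0.91), POLR2B (0.78) and SNRPD2 (0.77). Of the cell cycle and apoptosis lists, BCL2L1 (0.96), E2F1 (0.30), PLK1 (0.24) and UHRF1 (0.22) were positive and PMAIP1 (-0.18) and BCL2 (-0.46) negative. Of the WNT, intestinal and cholesterol lists, LSS (0.42), DVL3 (0.39), CCND1 (0.37) and FABP2 (0.22) were positive, and DVL1 (-0.31), TDGF1 (-0.37) and CA2 (-0.53) negative. Of the interferon and marker lists, CD3E (0.37) and OAS1 (0.36) were positive and IFIT3 (-0.15), THY1 (-0.27) and IFI44 (-0.69) negative. Outside the lists, among the genes with the smallest p, POU5F1 (0.54), PPP2R1A (0.45), ALOX15 (0.38), LEFTY1 (0.35), PPP2R2C (0.34) and CD1C (0.28) were positive. SFRP1 (-0.26), IL17RE (-0.29), LMO1 (-0.35), VHL (-0.39), EEF2K (-0.41), SMAD5 (-0.45), IRF5 (-0.47), ATP6V1G3 (-0.53), DTX3L (-0.55) and GNPDA1 (-0.69) were negative. As groups of shRNAs, ribosomal proteins (camera adjusted p = 0.00403), proteasome subunits (3.56e-07) and RNA polymerase II and splicing (1.15e-05) differed between the conditions at the preset correlation only, and with an estimated one they had adjusted p = 0.64, 0.0775 and 0.0775. In the 96 h RNA, the response to the EIF2B5 shRNA differed between APC states for WNT targets, ATF4 targets and cholesterol genes at the preset correlation only (camera adjusted p = 0.0276 each; 0.869 each with an estimated one), and 0 single genes were called.

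EIF2B5 shRNAs were depleted less with doxycycline than with ethanol. If all depleted shRNAs had merely dropped out less with doxycycline, genes with a like loss in ethanol would have positive differences too. The 193 such genes had a median difference of 0.01 (SD 0.268) with 97 above 0, which argues against this at that level of loss. Only the planned count, 0 of 193 with a difference as large as that of EIF2B5, was fixed in advance. EIF2B5 has the largest difference of all 5043 genes, so this count decides nothing. Among the 47 genes with the strongest loss in ethanol (medians under -2) the median difference was 0.41 and 44 lay above 0. These genes were picked by the ethanol values that the difference contains, which alone can raise it. Unequal numbers of cells at the start and a single off-target shRNA are excluded, by a median T0 difference of 0.04 for the 5 shRNAs and by a median of 1.24 for the other 4. Doxycycline itself, apart from APC, stays open because 0 libraries hold doxycycline-treated cells without the APC construct, so a lower need for EIF2B5 with restored APC is a hypothesis only.

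Targets of ATF4 were lower with doxycycline in the 96 h RNA, a call of the list that did not hold with the replicate block and an estimated correlation (adjusted p = 0.224). A fall due to 1 replicate is excluded, since the medians of the list in the 3 replicates were -0.53, -0.73 and -1.43. Doxycycline inhibits mitochondrial translation, which raises ATF4 targets, and the list's median of -0.92 has the opposite sign. That sign was given by the pattern, which is itself a fall, so it is no separate test. A shift of the whole scale would move lists of the same size and mean levels alike, and is excluded because the list lay 0.85 below them (a difference of -0.85, SD 0.0671 over 10000 random lists, which take genes as independent). In the 3 replicates it lay below genes of the same levels, by differences of -0.46, -0.72 and -1.33. Lower ATF4 activity with restored APC is a hypothesis only, while an effect of doxycycline itself stays untested in these libraries.

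On its most covered frame EIF2B5 fell less in footprints than in RNA with its shRNA. The choice of reading frame is a candidate explanation: over all frames of the gene the change in deficient cells was -2.22, near the -2.46 in RNA. In deficient cells the footprint change on the most covered frame lay 3.21 standard errors from the RNA change (distance 1.56, SE 0.488). This gap argues against low depth alone, but its SE takes separate fits as independent. The efficiency fit, which tests this gap in a single model, called 0 of 10162 genes there, so low depth is not excluded. In restored cells the footprint change lay 1.59 standard errors from the RNA change (distance 0.76, SE 0.478), so low depth stays open there too. No biological explanation was tested.

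For a comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The doxycycline effect at 96 h gave 443 calls in RNA and 380 in footprints, and in each case only 1 split, the real one, gave as many (highest other, 0). In RNA, 3 of the other splits part all 3 replicate pairs as the real one does, and they also gave 0. The EIF2B5 shRNA gave 1 call in RNA of deficient cells (highest other, 0) and 0 in restored cells (0), and in footprints 0 in deficient (493) and 0 in restored cells (0). The split with 493 calls exchanges a single library of each group, control B and shRNA C, and points to a structure of the samples. The drop-out counts were 19435 shRNAs and 3284 genes in ethanol and 20569 and 3568 with doxycycline (highest other, 0 each), and at T0 the count was 0 (0).

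The interactions called 0 genes, so each of the 100 splits drawn gives as many whatever it calls, and the count decides nothing about chance (highest other, 2582 in RNA and 1024 in footprints). The same holds for translational efficiency, with 0 calls and 60 splits drawn in each of the 4 comparisons (highest other, 636, 2, 1 and 40). The splits with 2582, 1024 and 636 calls point to a structure of the samples. For the difference in drop-out 8 of 100 splits gave as many shRNAs and 8 as many genes, which as a share does not exclude chance for either count (3219 against a highest other of 3888, and 500 against 645). Those 8 are the real split and 7 that keep the real T15 groups and exchange T0 libraries, which did not differ between the conditions. No split that changed the T15 groups gave as many.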

How the results depend on the processing

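The fits by footprint letter, over other reading frames and with TMM per assay, the list tests with a block, and the 48 h minimum abundance were chosen after the data were seen. Among values of single genes 4657 alternatives kept the direction of their test and the side of the threshold, 493 fell short of it, 34 newly passed it, 125 changed direction without a call and none reversed a call. List medians without a library are not in these counts. The 0 calls in translational efficiency (edgeR, 42, 66, 23 and 38 at an unadjusted p under 0.05) stayed 0 by every alternative run, DESeq2 and limma-voom included, as did those of the RNA interaction (422). These unadjusted counts lie below the share of 0.05 expected without any change, so 0 calls do not show that nothing changed. Where results moved, the cause was not tested.

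With the replicate number as a block, the RNA pairs gave 3692 calls for doxycycline (443 without), 191 for the EIF2B5 shRNA in deficient cells (1 without) and 14 in restored cells (0 without). With the footprint letter as a block the counts were 1080 for doxycycline (380 without), 11 and 3 for the shRNA in deficient and restored cells and 1 for their difference (0 without, each). Among the named genes this block changed only the footprint call of DDIT3 for doxycycline (-1.62, adjusted p = 0.0199; -1.82, 0.0525 without). With the screen's replicate number as a block, shRNAs changed in 19822 cases in ethanol, 20983 with doxycycline and 3983 for the difference, and 528 genes differed, all within 1.5 times the main counts. As a hint from the data, 11 of 12 footprint libraries were closest to their own letter (same-letter correlations 0.07 to 0.64, others -0.60 to 0.35) and 12 of 12 screen libraries to their own number (-0.09 to 0.34, others -0.23 to 0.13). DESeq2 called 1217, 40 and 20 genes in RNA for doxycycline and the shRNA in deficient and restored cells, and 816, 16 and 6 in footprints. A fit of the compared groups alone, with fewer libraries behind the spread, called 70 genes for doxycycline in RNA and 0 for the shRNA in deficient cells, and RLE scaling 0 for the latter too. Without a low-count filter 1 gene was called for the shRNA in restored cells in RNA, and over all reading frames 3 and 1 in footprints. Camera called 46 genes in ethanol, 11 with doxycycline and 3 for the difference in drop-out. T15 compared directly gave 8792 shRNAs and 1436 genes, and DESeq2 4637 shRNAs (59.9% up, against 48.5% by TMM). Of 66 list calls 12 held with an estimated correlation, 78 were made with the block, and 3 with both.

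Leaving out each replicate gave 132 (deficient 3) to 254 (restored 3) calls for doxycycline in RNA, 0 for the shRNA in deficient cells, and 0 to 1 (shRNA 2) in restored cells. In footprints it gave 175 (restored C) to 301 (deficient B) for doxycycline and 0 for the shRNA. For the difference in drop-out it gave 1513 (ethanol T0 1) to 6575 (doxycycline T15 3) shRNAs and 177 to 918 genes. Without doxycycline T0 1, 2 and 3 there were 1714, 1536 and 1630 shRNAs and 264, 218 and 235 genes, and without ethanol T0 2 and 3 there were 1680 and 1628 shRNAs and 242 and 212 genes. For drop-out itself the ranges were 17786 to 18877 shRNAs and 2894 to 3149 genes in ethanol, and 19268 to 21084 and 3221 to 3615 with doxycycline.

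At a log2 CPM of at least 1, 1441 genes passed in the authors' deposited table (1412 without). Other scalings, filters, tools, pseudocounts and left-out replicates were not run on it, since it holds no library values, and pseudocounts do not apply to the count fits. By the unblocked fits, simulated 2-fold changes were found in 0 of 97 genes in RNA and 22 of 100 in footprints, so these fits would miss most changes of that size gene by gene. This limit is not one of depth alone. In RNA the common dispersion was 0.18 without the replicate block and 0.0272 with it, and recovery with paired replicates was not simulated.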

Other observations

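The test of the hypothesis on upstream reading frames in the last paragraph was chosen after the result was seen.

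The footprint table also holds frames outside the coding ones: frames in 5' leaders (upstream frames), frames that overlap the coding start, and frames in 3' ends and noncoding RNA. Of 52069 frames tested by edgeR, doxycycline raised 235 and lowered 175 with the control shRNA. The upstream frame of IFRD1 on chromosome 7 (112450487 to 112450645, hg38), singled out after its values were seen, changed by -2.15 (adjusted p = 0.0468), beside -1.69 on its coding frame. ATF4, whose coding frame is reached through upstream frames that hold ribosomes back, had log2 changes of -2.09 on its truncated coding frame (adjusted p = 0.13 among all frames), -0.63 on the frame overlapping its start, and -0.60, 0.05 and -0.35 on its upstream frames. Its log2 ratio of coding to overlapping footprints was -1.02 ± 1.40 in deficient cells with the control shRNA and -2.17 ± 0.77 in restored ones (mean ± SD, n = 3), and the test did not separate the groups (exact permutation p = 0.2, two-sided, where 3 against 3 cannot go below 0.1).

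With the EIF2B5 shRNA in deficient cells, the median log2 change over upstream frames was 0.50 and over overlapping frames 0.38, against -0.01 over annotated coding frames. Within genes, upstream frames changed by 0.58 more than the coding frame (median of 3400 genes, 2675 of them higher). In restored cells the median within genes was -0.09 (1488 higher), and with doxycycline 0.08 (1878 higher). Single frames were rarely called with the shRNA in deficient cells, 0 rising and 4 falling by edgeR.

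A hypothesis is that less eIF2B raises the share of footprints in upstream frames. Scarce charged eIF2 lets ribosomes pass start codons and alters which are used, which by itself does not fix this direction. The share was 2.39 ± 0.755% with the shRNA and 1.75 ± 0.734% without in deficient cells, and 1.69 ± 0.203% and 1.75 ± 0.528% in restored cells (mean ± SD, n = 3). It was higher with the shRNA in 4 of 6 pairs of libraries of the same letter, with exact permutation p = 0.4 in deficient and 0.9 in restored cells (two-sided, smallest possible 0.1). The test left the hypothesis open. In deficient cells shRNA library A (3.09%), control library B (2.56%) and shRNA library B (2.48%) had the higher shares, against 1.59% in shRNA library C and 1.57% and 1.12% in control libraries A and C. The split of the libraries that gave 493 calls parts them in this way.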
